A study of Homo sapiens with 16 samples.

How the data were processed

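RNA and open chromatin were measured together in single nuclei of human retinal pigment epithelium (RPE), the pigmented cell layer beneath the retina, with the 10x Multiome assay. Per the labels, RPE of 4 healthy donors was scraped from the macula, the central area of sharpest vision, and from the temporal periphery after the neural retina had been removed. The samples were cryopreserved and thawed before nuclei were isolated, and 6000 nuclei were targeted per sample. Each donor gave 1 macular and 1 peripheral library, so the 8 libraries form 4 pairs, and every library has an RNA part and a chromatin part from the same nuclei.

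The processing notes of the labels name bcl2fastq, Cell Ranger ARC 2.0.0 on the genome build GRCh38, Seurat 3.1 and Signac 1.4.0. The labels state no filter on nuclei, and how the clusters were made is not stated. The authors deposited the raw count of each gene in each nucleus: unique molecular identifiers (UMIs) in the RNA part and chromatin fragments assigned to a gene, called gene activity, in the chromatin part. The deposited normalised values of both parts were the natural log of 1 plus the count divided by the nucleus total and multiplied by a fixed scale, 10000 in the RNA part. The authors also deposited a cluster number from 1 to 4 for every nucleus. The raw counts were used for every comparison, and the normalised values only for an alternative fit with limma.

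The deposited tables held 1707 nuclei, with at least 101 genes detected in every nucleus. Gene names were matched to current symbols and, where these failed, to older symbols in the RefSeq annotation. Of 36601 genes of the RNA part, 23463 matched a current symbol, 528 an older symbol and 12610 neither, and these last kept their deposited names. Of 19607 genes of the gene activity part, 18022 matched a current symbol, 801 an older symbol and 784 neither. Genes that mark sex, 110 in the RNA part and 62 in gene activity, were left out of every table. The library totals and depths reported here still include them, while the totals used for CPM do not. The 2 parts shared 18732 genes.

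The comparisons, the rule for named genes, 18 pathway lists and 15 lists of cell type markers were fixed before the data were examined. The authors' clusters were used as deposited. RPE markers were at lower levels in cluster 4 than in clusters 1 to 3, and cluster 4 also carried markers of other cell types, so the 1654 nuclei of clusters 1 to 3 were compared between regions, and the 53 nuclei of cluster 4 entered only the depths, the shares of nuclei and an alternative fit. Clusters 1 to 3 were kept together and were not given a cell type name, because the leading genes of cluster 3 included photoreceptor genes. The leading genes were ranked against the other nuclei, and those of clusters 1, 2 and 3 all held 0 RPE markers. Doublets were called per library with scrublet in scanpy 1.11.5, which marked 104 nuclei (6.09%), unevenly: in clusters 1 to 3 of donor 3 it left 17 of 36 macular and 21 of 43 peripheral nuclei. These stayed in the main comparison and were left out in an alternative. A separate clustering of the RNA counts used 2000 variable genes, 30 components, 15 neighbours and resolutions of 0.2, 0.5 and 1.

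Raw counts were summed per library and part. Each part was fitted with edgeR 4.0.16 (quasi-likelihood, TMM scaling, a filter on low counts by filterByExpr with a smallest count of 10 and a smallest total of 15), with region as the factor and donor as a block. The test was two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of a part, and genes under an adjusted p of 0.05 were called. Log2 fold changes are macula over periphery, so a negative value is higher in the periphery, and their standard errors (SE) were derived from the fold change and the F statistic. Levels are in CPM, given as the mean ± SD over 4 libraries, except for clusters, which were pooled over libraries. For single genes the totals are those of the tested genes alone, scaled by TMM. For clusters and classes of markers they are those of all genes, unscaled. The 2 scales are not comparable in RNA: macular WFDC1 is at 1493 CPM on the first and 1071 CPM on the second. Log2 CPM used a prior count of 2.

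Lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the 14 lists tested in RNA and the 32 tested in gene activity. Depths, shares of nuclei and correlations within a library were compared by two-sided exact permutation tests over 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286. Sign flips within donors have 16 arrangements, too few to reach the threshold. The fold changes of the 2 parts were correlated across genes by Spearman's rho and set beside the 7 other swaps of region labels within donors.

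The named genes were, per part, the called genes that moved the same way in all 4 donors with the 8 largest positive and the 8 largest negative fold changes, leaving out clone identifiers, ribosomal and mitochondrial genes. From each pathway list the member with the smallest p was added, with up to 2 further called members. WFDC1, CXCL14, IGFBP5 and RPE65 were named in any case. A gene named outside this rule is said to be so where it appears.

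Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, no donor block, each donor left out in turn, all deposited nuclei, nuclei with at least 500 UMIs, scrublet doublets left out, counts thinned to the shallowest library, and limma on the normalised values. Single clusters, the robust edgeR fit, the clustering at resolution 0.5 and the thinning of nuclei to 150 UMIs were added after the data had been seen. The pipeline was tested on simulated data with 200 genes changed. In RNA it called 22% of genes changed 2-fold and 96% of those changed 4-fold, with 6 unchanged genes among 124 calls. In gene activity it called 88% and 100%, with 16 unchanged genes among 204 calls. With no gene changed it made 0 calls in either part. The simulated genes were drawn independently of each other around the donor means, so differences shared by many genes of a library could not arise. The simulation therefore does not show how many calls such differences give in the real libraries. Analyses ran in Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3, and in R 4.3.3.

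The total per library over clusters 1 to 3 ran from 8776 to 636128 UMIs in RNA and from 1192738 to 12722014 counts in gene activity. The gene activity of genes that overlap on the genome shares fragments, so their values are not independent. Of 429 called genes with coordinates, 26 shared a stretch with another called gene once each gene had been widened by 2000 bp on both sides. Counting error is one part of the spread only. In fits with the donor block, differences in level between donors are taken out, and the spread of the regional difference over donors enters the test. The permutation tests and the fits without the block keep the spread between donors.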

Results

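The study compared RPE nuclei of the macula with those of the temporal periphery in the same 4 donors, in RNA and in chromatin. The macular libraries held 187, 172, 37 and 213 nuclei for donors 1 to 4, and the peripheral libraries held 106, 483, 45 and 464. The total RNA count was 219725, 358895, 10964 and 95804 UMIs in the macular libraries and 47807, 647976, 10850 and 618281 UMIs in the peripheral libraries. The total gene activity count was 4254640, 5673795, 1228064 and 5996850 in the macular libraries and 3995326, 12988946, 1776395 and 10252177 in the peripheral libraries. The RNA part was therefore shallow next to the chromatin part, and both libraries of donor 3 were small.

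Most nuclei lay in clusters that carried RPE transcripts. Clusters 1, 2 and 3 of the authors held 888, 406 and 360 nuclei, and in them the chloride channel gene BEST1 stood at 3218, 2932 and 3889 CPM. TRPM1, a cation channel gene, stood at 4936, 4003 and 4734 CPM, and RPE65, the isomerase of the visual cycle, at 1075, 1580 and 1226 CPM. Cluster 4 held 53 nuclei (27 macular and 26 peripheral) with lower levels of these genes, 503.7 CPM for BEST1, 599.3 CPM for TRPM1 and 121.6 CPM for RPE65. It also carried transcripts of cones (PDE6H at 521.1 CPM), Müller glia (WIF1 at 529.8 CPM) and immune cells (PTPRC at 555.8 CPM), which were near 0 in the other clusters. These levels are pooled, and the macular library of donor 1 gave more of the pooled UMIs than any other (219725 UMIs in all, 150685 in clusters 1 to 3). In a separate clustering at resolution 0.2, 11 cluster 4 nuclei, all of 1 macular library, formed a cluster with low RPE markers. The 42 others joined the cluster with high RPE markers. Cluster 4 made up 4.19% ± 4.47 (SD, n = 4) of macular and 2.92% ± 1.29 (SD, n = 4) of peripheral nuclei, a difference within the spread between donors (exact permutation p = 0.857). The difference turned to -0.92 percentage points without donor 1, whose macular library had the highest share. It was -10.73 points among nuclei with at least 500 UMIs, where the peripheral library of donor 3 had 1 nucleus of clusters 1 to 3 left and a cluster 4 share of 50%. In a separate clustering at resolution 1, clusters with low RPE markers held 19.66% ± 12.005 (SD, n = 4) of macular and 10.36% ± 9.24 of peripheral nuclei, higher in the macula in 4 of 4 donors (exact permutation p = 0.286). Most of these were a cluster of 166 nuclei whose RPE markers had a median log2 fold of -1.24 against the other nuclei, near the limit of -1, and 17 of them lay in the authors' cluster 4. No regional difference is read from the sizes of clusters 1 to 3, since genes that define them differed between regions in gene activity.

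Depth per nucleus was higher in the macular library of each of the 4 donors. The median was 652.5 ± 587.7 UMIs (SD, n = 4) in the macula and 369.6 ± 257.2 in the periphery (exact permutation p = 0.486). The median number of genes, also higher in the macula in 4 of 4 donors, was 461.8 ± 366.9 and 287.2 ± 196.8 (exact permutation p = 0.514), and 126.8 ± 5.85 and 127.0 ± 7.70 once nuclei had been thinned to 150 UMIs, with 22 macular and 106 peripheral nuclei too shallow for that. The median mitochondrial share of UMIs was lower in the macula in 4 of 4 donors, 1.54% ± 0.754 against 2.29% ± 1.36 (exact permutation p = 0.429). Gene activity per nucleus had medians of 29092 ± 5211 and 32977 ± 9884 counts (exact permutation p = 0.486), and this difference changed sign, to 1182 counts, without donor 1. The unpaired tests did not separate the regions, and the 4 pairs, which had a single sign for UMIs, genes and mitochondrial share, are too few for a paired test to reach the threshold.

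In RNA, the macula carried more transcript of WFDC1, which encodes a secreted protein with a protease inhibitor-like domain, and the periphery more transcript of elastin, of the melanosome fibril protein PMEL, and of INSYN2B, PDE4D and 4 further genes. WFDC1 (chromosome 16, 84294878 to 84329844 on GRCh38) had 1493 ± 570 CPM in the macula and 389 ± 379 CPM in the periphery, a log2 fold change of 2.72 ± 0.51 (SE, adjusted p = 0.00634). SPRY4-AS1, an RNA antisense to the growth factor signalling inhibitor gene SPRY4, was higher in the macula by 2.01 ± 0.38 (adjusted p = 0.00634). INSYN2B (chromosome 5, 169861303 to 169980495), which lies inside DOCK2, had 15.5 ± 14.1 CPM in the macula and 210 ± 82.6 CPM in the periphery, a log2 fold change of -3.69 ± 0.53 (adjusted p = 2.83e-04). ELN, the gene of elastin (chromosome 7, 74028173 to 74069907), had 89.6 ± 95.8 and 429 ± 151 CPM, a log2 fold change of -2.90 ± 0.45 (adjusted p = 4.89e-04). PMEL had 86.3 ± 43.1 and 407 ± 263 CPM, a log2 fold change of -2.51 ± 0.48 (adjusted p = 0.00634). The log2 fold change was -3.51 for PDE4D, a phosphodiesterase that degrades cAMP, -2.42 for KCNIP4, a regulator of potassium channels, and -2.29 for SLC4A10, a bicarbonate transporter. It was -2.17 for VEPH1 and -2.14 for the kinase gene HUNK. Each of these 10 genes had the same sign in 4 of 4 donors, although KCNIP4 was level in donor 1 (286.2 and 286.3 CPM). In donor 3, whose libraries were the smallest, several of them rested on a few UMIs. PDE4D and VEPH1 had 1 UMI in each library of donor 3 (115.19 CPM in the macula and 129.98 in the periphery), so their sign there comes from the scaling alone. INSYN2B and SLC4A10 had 0 CPM in the macula and 129.98 CPM in the periphery of that donor.

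Across the 2586 genes tested in RNA, 15 passed, 5 higher in the macula and 10 higher in the periphery, and 122 had an unadjusted p under 0.05. The size factors of DESeq2 gave 7 and 11, while limma on the normalised values, which changes the test and the averaging as well as the scaling, called 15 genes higher in the macula and 9 higher in the periphery. The median size of the log2 fold change among the calls was 2.42, and simulated changes of 2-fold were mostly missed at this depth. Outside the rule, and chosen after their values were seen, AC018742.1 (3.93), SLIT2 (3.21), PDE3A (2.01), AC109927.1 (-2.09) and STK24 (-1.74) passed as well. SLIT2 and PDE3A were higher in the macula in 3 of 4 donors. Without the donor block 6 genes passed, among them INSYN2B, PDE4D, ELN and SLC4A10. The number rested on single donors: it was 31 without donor 1, 1 without donor 2, 6 without donor 3 and 25 without donor 4. Without donor 2 none of the 5 named genes still tested passed, with log2 fold changes of 1.77 for RNA WFDC1, 1.60 for RNA SPRY4-AS1, -2.88 for RNA ELN, -2.21 for RNA PMEL and -1.65 for RNA KCNIP4. Without donor 3, INSYN2B, PDE4D and ELN passed and the 7 other named genes did not, with folds of similar size (2.91 for RNA WFDC1, 2.06 for RNA SPRY4-AS1, -2.57 for RNA PMEL and -2.48 for RNA KCNIP4).

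**Figure D1:**
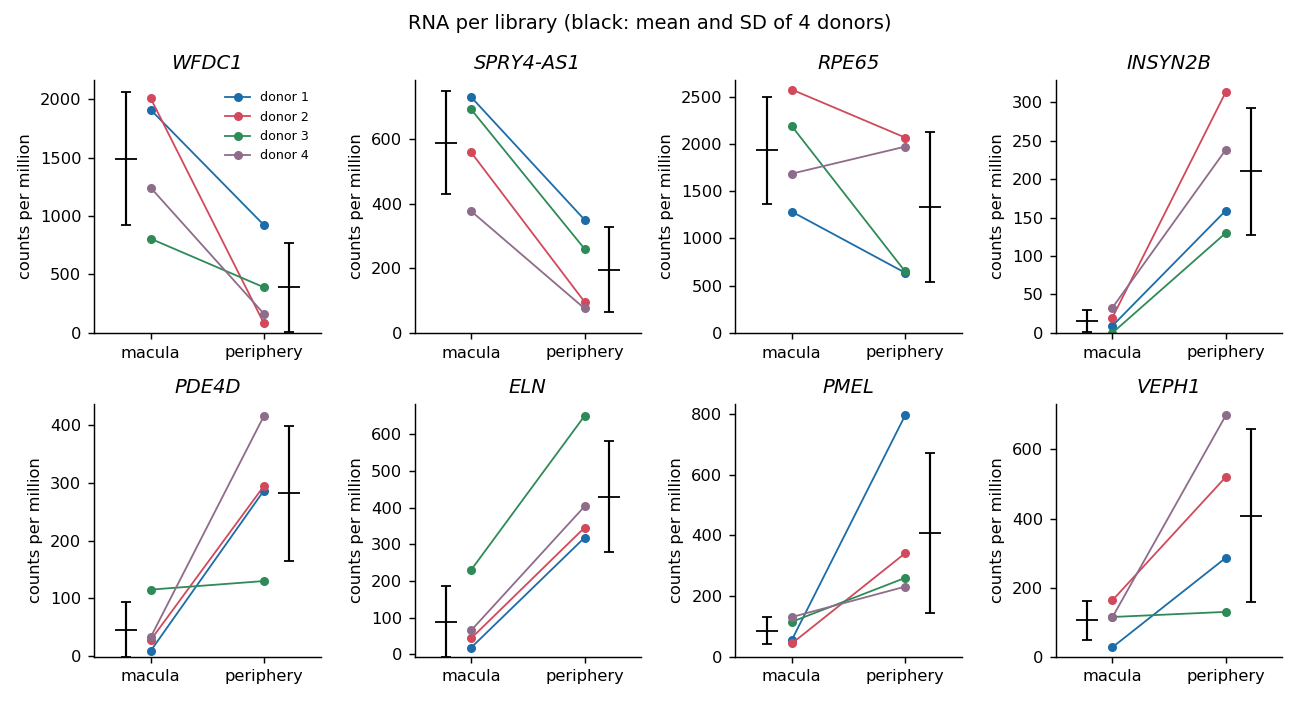
RNA levels of 8 genes in summed nuclei of clusters 1 to 3, in CPM on a linear axis, for the macular and the peripheral library of each donor (coloured points joined by lines), with the mean and SD of 4 libraries in black. WFDC1 and SPRY4-AS1 were higher in the macula and INSYN2B, PDE4D, ELN, PMEL and VEPH1 higher in the periphery in 4 of 4 donors, while RPE65 did not pass the test (adjusted p = 0.999). In donor 3, PDE4D and VEPH1 had 1 UMI in each library, so their sign there comes from the scaling alone.

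RPE65 and the other visual cycle genes did not pass the RNA test. RPE65 had 1933 ± 566 CPM in the macula and 1331 ± 796 in the periphery, a log2 fold change of 0.55 ± 0.37 (adjusted p = 0.999). Of 13 visual cycle genes tested, 0 passed and 11 had positive fold changes, with 0.71 for BCO1, which encodes an enzyme that cleaves beta-carotene. The camera adjusted p of this list was 0.594. Of 8 melanin and melanosome genes, 1 passed (PMEL) and 6 had negative fold changes, and 2 passed when adjusted over the list alone. The camera adjusted p was 0.529, from the smallest camera p of any list in RNA. Melanocytes share pigment genes with RPE, so melanocyte markers also on the RPE marker list were left out of their sum. The 8 others still held KIT, MITF of the RPE transcription factor list, and DCT and MLANA of the pigment list. These 8 markers summed to 201 ± 59.0 CPM in the macula and 306 ± 108 CPM in the periphery. This sum was lower in the macula in 4 of 4 donors (exact permutation p = 0.143, adjusted p = 0.321 over 15 marker classes). The secreted factors had 1 of 13 members called (WFDC1), also 1 when adjusted over the list alone. The markers of ciliary and iris epithelium, a list that holds WFDC1, summed to 1558 ± 260 CPM in the macula and 960 ± 215 CPM in the periphery, higher in the macula in 4 of 4 donors (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.321). Without WFDC1, the 9 other markers summed to 487 ± 157 CPM in the macula and 671 ± 196 CPM in the periphery, higher in the macula in 1 of 4 donors (exact permutation p = 0.257). The extracellular matrix list had 1 of 7 members called (ELN), also 1 when adjusted over the list alone.

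Ion and metabolite transport had 0 of 15 members called, and 1 when adjusted over the list alone, SLC4A5, a bicarbonate transporter with 1590 ± 1139 CPM in the macula and 3564 ± 1277 CPM in the periphery. Its log2 fold change was -1.41 ± 0.41 (adjusted p = 0.193), negative in 4 of 4 donors. RNA SLC4A5 passed without donor 4 (-1.87, adjusted p = 1.47e-05), with no filter on low counts (adjusted p = 0.0382) and by limma on the normalised values (adjusted p = 0.00113), and over all alternatives its adjusted p ran from 1.82e-06 to 1. Lipid metabolism had 0 of 14 called and 1 adjusted over the list alone, PPARGC1A, a coactivator of mitochondrial gene expression, with -1.48 ± 0.46 (adjusted p = 0.236). Of the 12 mitochondrially encoded genes 0 passed and 11 had positive fold changes, with 0.48 for MT-ND3. This list was called higher in the macula without donor 3 (camera adjusted p = 0.0367) and lower in the macula without donor 4 (camera adjusted p = 0.0201), both at the preset correlation alone. The estimated correlation of its genes over all donors was 0.916, and with it the adjusted p was 0.922. The immediate early and heat shock list had 3 tested members, with 1.52 for DNAJB1, and without donor 3, when more members could be tested, it was called higher in the macula at the preset correlation (camera adjusted p = 0.0299), and an estimated correlation was not run without that donor. RNA MT-ND3 and RNA DNAJB1 turned to -0.03 and -0.20 without donor 4.

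Further pathway lists had 0 members called in RNA, also when adjusted over the list alone. Their members with the smallest p had log2 fold changes of 0.53 for CRX (5 RPE transcription factors tested), -0.76 for SLC39A12 (5 antioxidant and metal handling genes) and -0.42 for EPB41L5 (10 junction and cytoskeleton genes). They were -0.73 for TSPAN10 (17 genes at macular degeneration loci), 0.81 for ENO2 (7 glycolysis genes), 0.23 for STAT2 (1 interferon and antigen presentation gene) and -0.20 for ZEB2 (2 mesenchymal transition genes). They were -0.81 for MERTK, the phagocytosis receptor (6 phagocytosis and lysosome genes), and 0.58 for BMP4 (2 regional patterning genes). Camera called 0 of 14 lists in RNA, with 1 at an unadjusted p under 0.05, and with an estimated correlation every adjusted p was 0.922. In RNA the median, the mean and the test differed in sign for the lists of antioxidant, junction, macular degeneration, phagocytosis and transcription factor genes and of RPE markers.

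In gene activity, the chromatin at 118 genes was more open in the macula and at 329 genes more open in the periphery, 447 of 17814 tested. The macula was led by CXCL14, a chemokine gene, and WFDC1. CXCL14 (chromosome 5, 135570679 to 135578991) had 55.6 ± 3.21 CPM in the macula and 20.3 ± 3.71 CPM in the periphery, a log2 fold change of 1.47 ± 0.14 (adjusted p = 4.06e-09). WFDC1 had 201 ± 29.4 and 83.0 ± 12.7 CPM, a log2 fold change of 1.31 ± 0.11 (adjusted p = 9.27e-11). VIM, the gene of the intermediate filament vimentin, had 42.5 ± 12.4 and 19.01 ± 6.96 CPM, a log2 fold change of 1.16 ± 0.14 (adjusted p = 2.07e-06). Log2 fold changes of 1.19 for the homeobox gene IRX6, 1.15 for TOR4A, 1.00 for TMEM88 and 1.00 for NAIP followed. The potassium channel gene KCNJ14 had 11.1 ± 3.55 and 5.06 CPM.

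TMEM51, KIT, ALDH1A3 and PAX6 were among the genes with higher gene activity in the periphery. TMEM51 (chromosome 1, 15152566 to 15220478) had 51.7 ± 16.2 CPM in the macula and 155 ± 9.37 CPM in the periphery, a log2 fold change of -1.67 ± 0.12 (adjusted p = 3.43e-12). KIT, a receptor tyrosine kinase gene (chromosome 4, 54657957 to 54740715), had 32.2 ± 8.40 and 101 ± 17.0 CPM, a log2 fold change of -1.62 ± 0.12 (adjusted p = 1.35e-11). ALDH1A3, which encodes an enzyme that makes retinoic acid (chromosome 15, 100879831 to 100916626), had 42.4 ± 9.52 and 109 ± 5.50 CPM, a log2 fold change of -1.43 ± 0.12 (adjusted p = 8.22e-11). PAX6, an eye field transcription factor gene (chromosome 11, 31789026 to 31817961), had 36.3 ± 13.2 and 81.3 ± 19.5 CPM, a log2 fold change of -1.27 ± 0.14 (adjusted p = 2.61e-07). The protease inhibitor gene TFPI2 (-1.76), CRISPLD1 (-1.40), the sphingosine phosphate receptor gene S1PR5 (-1.37) and the beta-adrenergic receptor gene ADRB1 (-1.32) were also higher in the periphery. REG1A (-1.58) rested on 125 counts over 8 libraries.

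Most regional differences in gene activity were smaller than these. The median size among the calls was 0.51 on the log2 scale, 27 calls reached a 2-fold difference (9 higher in the macula and 18 in the periphery), and 379 of the 447 moved the same way in 4 of 4 donors. At an unadjusted p under 0.05 there were 2408 genes. Without the donor block 10 genes passed, among them CXCL14, WFDC1, TMEM51, KIT, ALDH1A3, CRISPLD1, OCLN and MEIS1. The number was 175 without donor 1, 1164 without donor 2, 374 without donor 3 and 161 without donor 4, 187 by DESeq2, 115 among nuclei with at least 500 UMIs and 249 by limma on the normalised values. Leaving out scrublet doublets gave 268, with the nuclei of donor 3 falling from 36 to 17 in the macula and from 43 to 21 in the periphery, and thinning the libraries to the shallowest gave 235. Of the 35 named genes that passed, 11 were lost without donor 1 (among them KCNJ14, TMEM88 and REG1A), TMEM88 and IGFBP5 without donor 2, 4 without donor 3 and 10 without donor 4 (among them NAIP, ADRB1, IER3 and TYR). NAIP has near-copies in the genome, between which fragments cannot be assigned with certainty.

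**Figure D2:**
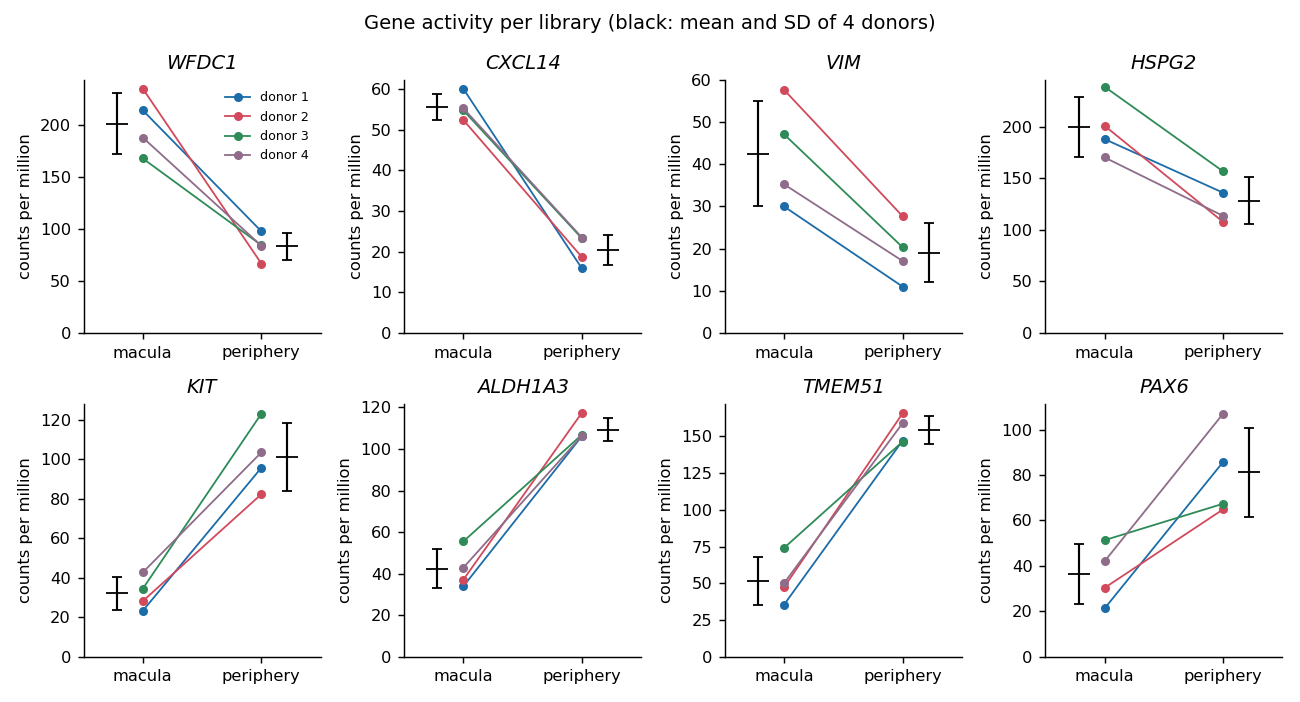
Gene activity of 8 genes in summed nuclei of clusters 1 to 3, in CPM on a linear axis, for the macular and the peripheral library of each donor (coloured points joined by lines), with the mean and SD of 4 libraries in black. WFDC1, CXCL14, VIM and HSPG2 were higher in the macula and KIT, ALDH1A3, TMEM51 and PAX6 higher in the periphery in 4 of 4 donors.

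Among the fixed lists, regional patterning held the largest number of called genes in gene activity. Of its 29 tested members 1 was higher in the macula and 7 higher in the periphery, and adjusted over the list alone 1 and 9 were. Camera gave the list p = 0.00164 (adjusted p = 0.0526, and adjusted p = 0.883 with an estimated correlation). The members higher in the periphery included ALDH1A3, the homeobox gene MEIS1 (-0.69 ± 0.10) and the nuclear receptor gene NR2F1 (-0.67 ± 0.13). Chosen after their values were seen, the others were TBX2 (-1.10), IRX3 (-0.84), CYP26A1, which encodes an enzyme that degrades retinoic acid (-0.74), and CYP1B1 (-0.41), while EFNB2, an ephrin gene, was higher in the macula (0.50). The list passed without the donor block (camera adjusted p = 0.00991), without donor 3 (camera adjusted p = 0.0119) and over all deposited nuclei (camera adjusted p = 0.0459). Of 15 RPE transcription factors tested, PAX6 and NR2F1 passed, both higher in the periphery, and 5 passed when adjusted over the list alone.

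Genes of secreted factors and matrix differed in both directions. Of 34 secreted factors 3 were higher in the macula and 4 in the periphery, and 9 passed when adjusted over the list alone (camera adjusted p = 0.998). CXCL14 and WFDC1 led the first, with FGF1 (0.49), and TFPI2 the second, with IGFBP5, an insulin-like growth factor binding protein gene at 72.1 ± 9.36 CPM in the macula and 97.2 ± 16.1 CPM in the periphery (-0.47 ± 0.12, adjusted p = 0.0213). SFRP1 (-0.74) and PTN (-0.60), chosen with FGF1 after their values were seen, were the other members higher in the periphery. Of 35 extracellular matrix genes, HSPG2, the gene of the basement membrane proteoglycan perlecan, was higher in the macula (0.65 ± 0.09, adjusted p = 2.46e-05). ELN (-0.67 ± 0.10), FBN2 (-0.43) and ADAMTS9 (-0.36) were higher in the periphery, and 7 members passed when adjusted over the list alone (camera adjusted p = 0.968). Of 18 mesenchymal transition genes VIM passed, and 4 did when adjusted over the list alone (camera adjusted p = 0.429).

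Pigment, junction and stress genes had fewer calls. Of 18 melanin and melanosome genes, TYR, the gene of tyrosinase (-0.68 ± 0.15), and OCA2 (-0.38) were higher in the periphery, also 2 when adjusted over the list alone, and 14 had negative fold changes. The camera adjusted p of the pigment genes was 0.228. Of 21 junction and cytoskeleton genes, OCLN, the tight junction gene of occludin (-0.98 ± 0.14, adjusted p = 1.29e-05), and CLDN10 (-0.46) were higher in the periphery, also 2 when adjusted over the list alone (camera adjusted p = 0.306). Of 34 antioxidant and metal handling genes, MT1G (-0.75) and SOD3 (-0.67) were higher in the periphery, with 3 adjusted over the list alone (camera adjusted p = 0.458). Of 28 immediate early and heat shock genes, IER3 was higher in the macula (0.68 ± 0.15) and 24 had positive fold changes, with 1 called adjusted over the list alone. This list had a camera p of 0.00375 (adjusted p = 0.0595). It passed without donor 2 (camera adjusted p = 0.00716), without the donor block (camera adjusted p = 0.0463) and over all nuclei (camera adjusted p = 0.0459), and did not with an estimated correlation (adjusted p = 0.883). Of 15 visual cycle genes BCO1 was higher in the macula (0.41, in 3 of 4 donors), 3 passed when adjusted over the list alone, and RPE65 had 114 ± 22.4 and 106 ± 20.4 CPM (0.10 ± 0.10, adjusted p = 0.727).

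Of 24 phagocytosis genes GAS6, a ligand of the receptor MERTK, was higher in the periphery (-0.77 ± 0.13), also 1 adjusted over the list alone. Of 36 lipid metabolism genes PPARGC1A was higher in the periphery (-0.39), also 1 adjusted over the list alone. ADAMTS9, higher in the periphery, is also on the list of genes at macular degeneration loci. Glycolysis (23 tested, PFKFB3 at 0.21), interferon and antigen presentation (25 tested, OAS1 at 0.79) and ion and metabolite transport (22 tested, CFTR at -0.39) had 0 called, and 0, 0 and 3 adjusted over the list alone. Camera called 0 of 32 lists in gene activity, with 7 at an unadjusted p under 0.05, and the smallest adjusted p with an estimated correlation was 0.883. The median, the mean and the test differed in sign for the matrix, macular degeneration and secreted factor lists, among others, and for the markers of glia, macrophages and endothelial cells.

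Markers of other cell types moved in both directions in gene activity and no marker list passed. The melanocyte list had KIT and TYR called of 11, both higher in the periphery, and the mast cell list had KIT of 6. The camera adjusted p was 0.139 for melanocytes and 0.0595 for mast cells. The mast cell list passed without donor 2 (camera adjusted p = 0.0319) and without the donor block (camera adjusted p = 0.0463), with KIT its single called member, and did not with an estimated correlation (adjusted p = 0.883). The glia list had VIM higher in the macula and S100B (-0.79) higher in the periphery, and S100B is also on the Schwann cell list. The cone list had GUCA1C (-0.93) and KCNB2 (-0.42) called of 9, both higher in the periphery, and the fibroblast list PDGFRA (-0.50) of 12. The camera adjusted p was 0.159 for Schwann cells and 0.139 for cones. These 4 genes were chosen after their values were seen. The lists of endothelial cells, pericytes, macrophages, T cells and B cells had 0 members called. Rod markers had 1 member called in each direction, markers of ciliary and iris epithelium also 1 in each (WFDC1 and PAX6), and markers of inner retinal neurons 1 higher in the macula and 2 in the periphery.

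The regional differences of RNA and of gene activity went in the same direction for the genes called in both. Of the 15 genes called in RNA 9 had a gene activity value, and all 9 had the same direction there. WFDC1, INSYN2B, ELN, VEPH1, HUNK and STK24 were called in both parts, with gene activity fold changes of 1.31, -0.97, -0.67, -0.58, -0.50 and -0.51. The gene activity of INSYN2B shares fragments with DOCK2, inside which it lies and which was itself higher in the periphery (-0.58). PMEL, called in RNA, had a gene activity fold change of -0.20 (adjusted p = 0.421). Of the 447 genes called in gene activity 60 were tested in RNA, and 54 of them (90%) had the same direction. CXCL14 and IGFBP5 had too few RNA counts to be tested.

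**Figure D3:**
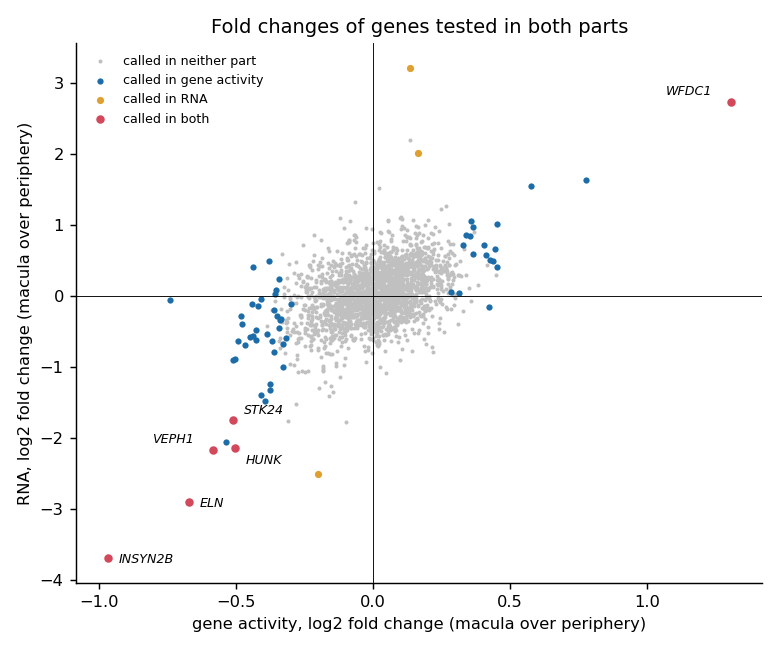
Log2 fold change (macula over periphery) of each gene tested in both parts, in gene activity on the horizontal axis and in RNA on the vertical axis. The 6 genes called in both parts are labelled, and over all 2278 genes the rank correlation was 0.398.

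Over the 2278 genes tested in both parts, the fold changes had a Spearman correlation of 0.398, a value across genes, which are not independent replicates. The 7 other swaps of region labels within donors gave -0.124 to 0.339. The highest swapped donor 3 alone, and so kept the real labels in the other donors. The correlation was 0.293 without donor 2 and 0.214 without donor 4, and 0.257 within cluster 1. Within single libraries, RNA level and gene activity correlated across genes at 0.495 ± 0.098 (SD, n = 4) in the macula and 0.493 ± 0.119 (SD, n = 4) in the periphery, a difference that was not detectable (exact permutation p = 1) and that changed sign without donor 1 and without donor 3. The lowest library had 0.339 and the highest 0.615. Over genes with at least 10 counts in both parts the correlations were 0.359 ± 0.216 in the macula and 0.297 ± 0.335 in the periphery, and the lowest library had -0.146.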

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

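Tests of the cluster shares, of melanocyte markers and of depth were chosen only after the results were seen. Among 150 groups of 4 libraries, 7 had a single library far from the other 3, where chance gives about 7.5, so the list below holds no more than chance alone would give.

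Cluster 3 made up 8.11% of the macular nuclei of donor 3, which are 37 in all, and 29.95% to 31.98% in the other macular libraries. The gene activity of TOR4A in the macular library of donor 2 was 17.86 CPM (11.78 to 12.44 in the others). NAIP in the macular library of donor 3 was at 29.46 CPM (11.41 to 11.65 in the others). ALDH1A3 in the peripheral library of donor 2 was at 117.5 CPM (106.2 to 106.9 in the others). The gene activity ADRB1 had in the peripheral library of donor 4 was 14.86 CPM (4.85 to 6.39 in the others), and its call was lost without donor 4 (log2 fold change -1.12). GAS6 in the peripheral library of donor 3 was at 70.28 CPM (78.49 to 80.18 in the others) and MEIS1 in the same library at 179.5 CPM (193.4 to 195.0 in the others).

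The first pattern weighed is the number of genes that differed between regions. In RNA, 3 of 20 distinct splits of the 8 libraries, the real one included, gave at least the 15 calls of the real one. The highest other gave 16, in a split that swaps the regions of donor 3 alone. The other split with 15 calls compares the real regions in donors 2 and 4. These splits keep the real contrast in some donors, so they cannot show what chance gives, and chance is not excluded for the number of RNA calls. In gene activity the real split gave 447 (1 of 20 distinct splits) and the highest other 359, in a split that parts 2 pairs of donors. That split compares the real regions in donors 1 and 4, so it does not show what chance gives either. The highest of the splits that part all 4 pairs gave 59, and the splits are too few for a share under 0.05. Different shares of clusters 1 to 3 in the regions are argued against, since fold changes at fixed shares were 1.043 times those without in RNA (quartiles 0.945 to 1.105) and 0.939 times in gene activity (quartiles 0.853 to 1.011). A difference between the regions themselves stays open and was not tested apart from other differences between the dissected samples.

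The second pattern is the larger number of calls in gene activity than in RNA. Lower depth of the RNA part may account for it: gene activity thinned to the RNA total of each library gave 11 calls among 3977 genes tested, against 15 in RNA. Whether RNA and chromatin also differ in how far the regions are apart stays open.

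The third pattern is the higher peripheral gene activity of KIT, ALDH1A3 and PAX6. A minority of peripheral nuclei of another cell type is argued against only where its share is smaller than the rises below. A larger minority is not excluded. At 10000 counts per nucleus, KIT had a count in 23.0% ± 5.54 of macular and 59.9% ± 6.63 of peripheral nuclei (46.7% and 82.5% unthinned). The smallest rise of the 3 genes was 26.27 percentage points for PAX6 (SD 5.93, n = 4). In that comparison 47 macular and 135 peripheral nuclei were too shallow, and RPE65 had 67.9% and 64.9%. Melanocytes as the whole source of the KIT difference are argued against by EDNRB, PAX3, MLANA, DCT and TYR. These are the 5 other melanocyte markers with a macular level no higher than that of KIT. Their median log2 fold change was -0.096 (SD 0.316). However, TYR (-0.68) was itself called. Melanocyte markers not on the RPE marker list were also lower in macular RNA in 4 of 4 donors (201 and 306 CPM), a sum that holds KIT itself and MITF, DCT and MLANA. A small contribution therefore stays open. A regional difference of the RPE nuclei themselves is a hypothesis that stays open, as do other differences between the dissected samples.

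For the lists, the real split gave 0 in RNA and 0 in gene activity, so all 20 splits gave as many (20 and 20), and the highest other gave 2 and 5. For the correlation of fold changes between RNA and gene activity, the real split gave 0.398 (1 of 20) and the highest other 0.355, and the splits are too few for a share under 0.05.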

How the results depend on the processing

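Fits within single clusters, the robust edgeR fit, the separate clustering at resolution 0.5 and the thinning of nuclei to 150 UMIs were chosen only after the results were seen, and the other alternatives before. The 15 RNA and 447 gene activity calls, where still tested, kept their direction under every alternative for RNA, and for gene activity except for some genes among nuclei with at least 500 UMIs (427 of 444 kept it), in cluster 2 (404 of 425) and in cluster 3 (439 of 443). Depth limits the RNA part: with the libraries thinned to the shallowest, 57 genes were tested by edgeR, 0 passed and 2 had an unadjusted p under 0.05.

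The donor block, taken from the labels, mattered for the counts: without it 6 genes passed in RNA, 10 in gene activity, 0 lists in RNA and 3 lists in gene activity. To look at the pairing, the mean of each gene over the libraries of a region was taken from its log2 CPM. The deviations left, not the levels, were correlated across genes between macular and peripheral libraries. Same-donor libraries gave 0.12, 0.47, 0.17 and 0.04 in RNA (other pairs -0.23 to 0.2). They gave 0.16, 0.49, 0.17 and 0.54 in gene activity (other pairs -0.51 to 0.3). Leaving out 1 donor gave 1 to 31 RNA calls, 161 to 1164 gene activity calls, 0 to 2 lists in RNA, 0 to 2 lists in gene activity and correlations of fold changes of 0.214 to 0.37. RNA gave 36 calls with no filter on low counts, 24 by limma, 9 with at least 500 UMIs and 8 in cluster 1. Gene activity gave 187 by DESeq2, 249 by limma, 235 thinned, 268 without scrublet doublets, 115 with at least 500 UMIs, and 89, 31 and 37 in clusters 1, 2 and 3. Over all deposited nuclei 2 lists passed in gene activity, and in cluster 1 the correlation of fold changes was 0.257. The cause was not tested, beyond the fewer nuclei or genes that some of these settings leave.

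These differences changed sign: genes per nucleus, -0.25 at 150 UMIs; gene activity counts per nucleus, -6989 to 1182 when leaving out 1 donor; the cluster 4 share, -0.9213 to 2.281 percentage points when leaving out 1 donor and -10.73 with at least 500 UMIs (1 nucleus of clusters 1 to 3 left in a peripheral library). In the separate clustering, the share with low RPE markers differed by 1.471, 1.604 and 9.298 points at resolutions 0.2, 0.5 and 1. At 0.2 and 0.5 these were 11 and 12 nuclei, all of 1 macular library. The cluster 3 share ran from -1.072 to 13.73 and the RNA and gene activity correlation within libraries from -0.02132 to 0.02128, each when leaving out 1 donor. Among named genes none of which was called except FBN2, RNA DNAJB1 ran from -0.196 to 2.786 and RNA MT-ND3 from -0.028 to 0.761 when leaving out 1 donor, ZEB2 was 0.078 by limma, FBN2 0.065 in cluster 3 and RPE65 gene activity -0.031 in cluster 1. The cause was not tested.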

Other observations

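All tests in this part were chosen only after the results of the pooled nuclei were seen. Several of the regional differences were also called within each of the authors' clusters 1 to 3. In gene activity, WFDC1 had log2 fold changes of 1.15, 1.54 and 1.53 in clusters 1, 2 and 3, and CXCL14 had 1.37, 1.65 and 1.36. KIT had -1.37, -1.71 and -1.92, ALDH1A3 had -1.43, -1.56 and -1.50, TMEM51 had -1.66, -1.88 and -1.68, and PAX6 had -1.20, -1.09 and -1.52, each called by edgeR in every cluster. In RNA, WFDC1 had 2.33, 3.63 and 2.37 and was called in every cluster, while ELN was tested in cluster 2 alone (-3.08, adjusted p = 6.64e-04) and INSYN2B, PDE4D and PMEL had too few counts to be tested in any single cluster. IRX6, called in the gene activity of the pooled nuclei, had similar folds in clusters 1, 2 and 3 (1.12, 1.46 and 1.11) and passed in none of them (adjusted p = 0.0927, 0.177 and 0.529), and TFPI2 was called in clusters 1 and 3 and not tested in cluster 2. Differences between the clusters in these values were not tested. Single clusters of donor 3 were small, with 3 nuclei and 926 UMIs in cluster 3 of its macular library.

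SLC4A5, a bicarbonate transporter gene that did not pass in the main test of the pooled nuclei but did under 3 alternatives (without donor 4, with no filter on low counts and by limma), was higher in the periphery in the RNA of cluster 1 (log2 fold change -1.86 ± 0.24, edgeR adjusted p = 1.82e-06) and of cluster 3 (-1.91 ± 0.35, adjusted p = 1.58e-05). In cluster 2 it had -1.21 ± 0.46 (adjusted p = 0.443). These fits tested 283, 257 and 1214 genes, fewer than the 2586 of the pooled nuclei. Donor 3 added little to them: its macular library had 926 UMIs in cluster 3, and its peripheral library had 3153 UMIs in cluster 1.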
